A study of Mus musculus with 16 samples.

How the data were processed

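Total lung RNA of 16 mouse samples was measured on Affymetrix whole-transcript arrays, 1 array per sample. Mice on a C57BL/6 background received crystalline silica (CS) or phosphate-buffered saline (PBS) into the trachea. The mice were wild type or null for BLT1, the high-affinity receptor for the neutrophil attractant leukotriene B4, which is encoded by Ltb4r1. Lungs without a tumor allele were taken at day 2 and lungs with the KRasLA1 allele at day 60. KRasLA1 is a latent oncogenic allele that is switched on by spontaneous recombination and gives rise to lung tumors. Each of the 4 CS groups holds 3 lungs, which the labels call biological replicates, and each of the 4 PBS groups is 1 array of RNA pooled from 3 mice. The labels give no animal numbers, so p-values measure only the spread between these samples, part of which may be technical. Day and KRasLA1 go together in this series and cannot be told apart.

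The deposited values are log2 expression values per probe set, with a median per array between 8.25 and 8.34. Arrays were normalized with RMA in Partek 6.6, per the submitters' processing notes. The order of steps and the exact array design are not given in the sources used here. RMA scales all arrays to 1 distribution, so a change in total RNA per lung would not be seen, and it draws dim probe sets towards a floor, which understates their changes. No detection calls were used here. The closest pair of arrays differed by an SD of 0.22 log2 units over probe sets, and no array was a copy of another. No column of the table was left unused.

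Probe sets were named through the platform annotation supplied with the values. Of 35556 probe sets, 21789 carried 1 gene symbol, 1621 several and 12146 none. The gene identifiers of 21698 named probe sets were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols had to be updated. That table served only for names and for which genes share a chromosome. Probe sets with several symbols or none were left out of gene comparisons. For each of 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 19938 genes. The mutated gene of the KRasLA1 allele and 1 gene of the panel described below were not analysed here.

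Group means were fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). The 8 residual degrees of freedom come from the CS lungs alone and were joined by 5.4 prior degrees of freedom. A PBS pool has no replicate, so it was assumed to vary like a CS lung. A pool of 3 mice averages over animals and may vary less. The number of arrays limits the precision: the median standard error over genes was 0.14 log2 units for CS lungs against 1 pool, 0.10 for responses averaged over the BLT1 genotypes and for differences between BLT1 genotypes, and 0.20 for interactions. The 12 contrasts were tested two-sided, each with Benjamini-Hochberg adjustment over the 19938 genes and a threshold of 0.05: the silica response in each of the 4 genotypes, its mean over BLT1 genotypes at each day, the difference between BLT1 genotypes after silica at each day, the BLT1 by silica interaction at each day, the difference of the mean responses between days, and the difference between the PBS pools of the 2 days. All contrasts use the same variance estimate of a gene, so lists of called genes are not independent. Some sharing above that of independent lists is therefore built in. Every p-value and adjusted p of a gene below is from limma, and every error is a standard error unless called SD.

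The design, the alternatives, the gene lists and the rule for which genes are named were fixed before the data were examined. The rule takes Ltb4r1, a panel of 22 inflammatory genes, and for each comparison up to 8 genes with the largest rise and up to 8 with the largest fall past the threshold. For mean responses these had to go the same way in both genotypes, and for BLT1 differences the lungs of the genotypes could not overlap. Where no gene passed, the 5 with the smallest p are named. From each list called in a comparison up to 4 members with the smallest p may be named, and up to 2 from a list that was not called. Predicted genes, small RNAs and receptor segments were not named under the rule for largest changes. Genes named outside the rule are said to be so.

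Gene groups were tested with camera at an inter-gene correlation of 0.01, with adjustment over 41 lists in each comparison, and again with an estimated correlation and with fry. The lists cover chemokines, cytokines and other inflammatory pathways, leukocyte classes, lung cell classes, tumor-related programs, and tissues that a dissected lung could carry along. They hold 670 members, of which 615 were matched to a measured gene, 16 only to probe sets with several genes, and 39 to none. Lists share some members, and a list marks a program or cell class only as far as its genes are specific to it. A count "adjusted over the list alone" applies the adjustment to the members of that list. Over the 12 comparisons 251 list calls were made with the preset correlation, 35 with an estimated correlation and 112 with fry. The latter asks only whether the members of a list change in a comparison, without setting them against the other genes.

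Replicate numbers are shared by the groups in the labels. After removal of group means, same-numbered CS lungs of the BLT1 genotypes correlated across genes at 0.426, 0.2 and 0.345 at day 2 and at 0.091, 0.01 and 0.055 at day 60. Genes are not independent replicates. By a limit of 0.1 for every pair the numbers pair the day 2 lungs, a pairing that comes from the values alone, and do not pair the day 60 lungs. A block for the number was fitted over the 12 CS arrays as planned, and over all 16 arrays at day 2 after the values were seen. In the latter a PBS pool belongs to no block, so that fit takes the spread between blocks out of the CS lungs alone and its errors for silica responses are too small.

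The alternatives were a filter to genes at or above the median level, the mean of a gene's probe sets, repeated quantile normalization, median centring, cyclic loess, moderation without a trend, robust moderation, array weights, the 8 arrays of 1 day, a minimum of 1.5-fold, an additive model with and without each PBS pool, the blocks, and leaving out each CS lung in turn. Others were added after the values were seen: the male share of each array as a covariate at day 60, the PBS pool of the other BLT1 genotype at day 2, the BLT1 differences without genes on the chromosome of Ltb4r1, and the day 2 block over all arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and figures.

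The fit was tested on simulated data of the same 19938 genes with 100 genes changed 2-fold and 100 changed 4-fold. Of the 2-fold changes it recovered 93% for the day 2 response of BLT1+/+ lungs, 100% for the mean day 2 response, 98% for the day 2 BLT1 difference and 67% for the day 2 interaction. Of the 4-fold changes it recovered 100% in each of these. False calls made up 6.8%, 5.7%, 3.4% and 6.2% of the calls in that order. The simulated noise was independent between genes and arrays and had the same SD for pools and CS lungs. These rates therefore do not test the assumption made for the pools, nor the effect of correlated genes or paired lungs.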

Results

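The series asked how crystalline silica acts on the mouse lung and on lungs that carry the KRasLA1 tumor allele, and whether this depends on BLT1. Total lung RNA was profiled in 8 groups, 16 arrays in all. BLT1+/+ and BLT1-/- lungs were taken at day 2, and BLT1+/+KRasLA1 and BLT1-/-KRasLA1 lungs at day 60, each as 3 CS lungs and 1 PBS pool of 3 mice. Values are log2 expression levels of 19938 genes. The first 3 principal components of the arrays held 34.2%, 24.3% and 11.1% of the variance.

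Ltb4r1, the gene of BLT1 (probe set 10415392), lay between 7.21 and 7.63 on all 16 arrays, at the 26.4th percentile of gene levels. After silica it differed between BLT1-/- and BLT1+/+ lungs by -0.19 ± 0.08 at day 2 (adjusted p = 0.522) and by -0.08 ± 0.08 at day 60 (adjusted p = 0.967). Whether this probe set lies inside the deleted part of the gene is not given in the sources used here, so it does not check the labels. Sex-linked genes set 3 of the arrays apart. Y-linked Eif2s3y was at 10.09 in BLT1+/+KRasLA1 CS replicate 2, where Xist, the RNA of the inactive X chromosome, was at 6.61. The day 60 PBS pools showed both, with Eif2s3y at 9.68 in the BLT1+/+ pool and 9.04 in the BLT1-/- pool, and Xist at 12.32 and 12.16. On the other 13 arrays Eif2s3y lay between 4.27 and 4.74 and Xist between 12.75 and 13.06. Read on the linear scale of Eif2s3y, with that lung as 1, the pools had a male share of 0.744 and 0.469. This share rests on a single gene and a single lung. By Xist, which was lower in the BLT1-/- pool, the order of the pools would be reversed.

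At day 2 an acute phase gene, chemokine genes and Il6 had risen most in the lung after silica, averaged over both BLT1 genotypes. Saa3, an acute phase serum amyloid A (probe set 10563597), rose most, by 4.91 ± 0.22 on the log2 scale (adjusted p = 1.11e-07). The neutrophil attractant Cxcl2 rose 19.8-fold (4.31 ± 0.49), Ccl3 14.5-fold (3.85 ± 0.32), the cytokine Il6 13.3-fold (3.73 ± 0.27) and the metalloprotease inhibitor Timp1 10.3-fold (3.36 ± 0.24). The monocyte attractant Ccl2 rose by 3.02 ± 0.32, the cell adhesion molecule Chl1 by 3.01 and the interferon-induced chemokine Cxcl10 by 3.01 ± 0.45. The B cell receptor component Cd79a fell most, by 1.58 ± 0.24 on the log2 scale (2.98-fold). Ms4a1 (CD20) changed by -1.55, H2-Ob by -1.53, Bank1 by -1.51, Igfbp3 by -1.47, Ly6d by -1.45, Ces1g by -1.32 and Ms4a4b by -1.30. All of these had the same sign in 6 of 6 lungs. Of the panel of inflammatory genes, Cxcl5 (1.71), Mmp12 (1.65 ± 0.21), Lcn2 (1.07 ± 0.05), Cxcl1 (1.07) and Retnla (0.71) also rose. Arg1 (1.67, adjusted p = 0.0241) and Tnf (1.42, adjusted p = 0.00491) rose too, each in 6 of 6 lungs. The neutrophil gene S100a8 was at -0.14 ± 0.36 (4 of 6 lungs, adjusted p = 0.867), S100a9 at -0.21, Mmp8 at 0.37, Mmp9 at -0.19 and Chil3 at 0.21. None of these passed. S100a8, S100a9 and Mmp9 were higher in the day 2 than in the day 60 PBS pools, as given below, so their day 2 values are set against a higher control. Il1b was at 1.04 ± 0.34 in 6 of 6 lungs (adjusted p = 0.0620, and 0.0456 with the day 2 replicate block). The leukotriene enzymes Alox5 (0.03), Lta4h (0.03) and Alox5ap (-0.11) did not pass. In all, 1602 genes were higher and 871 lower, 508 and 188 of them by at least 1.5-fold. The 8 day 2 arrays alone gave 1589 genes, and additive fits gave 426 without the BLT1+/+ pool and 96 without the BLT1-/- pool. Without either pool Cd79a, H2-Ob, Bank1, Ms4a4b, Arg1 and Cxcl1 were lost (adjusted p from 0.0539 to 0.137), without the BLT1+/+ pool also Tnf (0.64, 0.329), and without the BLT1-/- pool also Ms4a1 (-1.69, 0.0539) and Igfbp3 (-1.15, 0.143).

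Of 23 chemokine genes, 17 rose and 1 fell at day 2, with 20 and 1 adjusted over the list alone and a median of 0.83. Cxcl13, which attracts B cells, rose by 2.71. Acute phase proteins rose in 8 of 12 (10 adjusted over the list alone), among them Orm1 (2.97) and Lrg1 (1.16), and inflammatory cytokines in 8 of 22 (9), among them Il1rn (2.22), Il1a (2.09) and Il33 (1.23). Extracellular matrix genes rose in 11 of 21 and fell in 1 (11 and 1 adjusted over the list alone), with Tnc at 2.80 and Vcan at 1.25. Adenoma and epithelial plasticity genes rose in 11 of 19, with 11 higher and 1 lower adjusted over the list alone, among them Slc5a1 (1.19), Cldn4 (1.22) and Krt8 (0.65). NK and cytotoxic markers fell in 10 of 13 (12 adjusted over the list alone), with Nkg7 at -1.13 and Gzma, a cytotoxic granule protease, at -1.02. These 6 lists had an adjusted p = 0.128 each with an estimated correlation, so their camera calls were lost with it. All 25 cell cycle genes rose (25 adjusted over the list alone, median 1.34), with the proliferation marker Mki67 at 1.84 and Top2a at 1.88. Dendritic cell and MHC class II genes fell in 12 of 19 and rose in 2 (13 and 3 adjusted over the list alone), with H2-Ab1 at -0.64. Both had an adjusted p = 0.144 with an estimated correlation. B cell markers fell in 12 of 15 (13 adjusted over the list alone, median -1.03), with Cd79b at -1.12 and an adjusted p = 0.153 with an estimated correlation. T cell markers fell in 11 of 20 (13 adjusted over the list alone), with Cd3g at -0.90 and an adjusted p = 0.213 with an estimated correlation. Cd3g was higher in the day 2 than in the day 60 PBS pools, as given below, so its fall is set against a higher control. Oxidative stress genes rose in 11 of 16 and fell in 1 (12 and 1 adjusted over the list alone). Among them were the cystine transporter Slc7a11 (2.89), the metallothionein Mt2 (1.51) and Sod2 (0.60), with an adjusted p = 0.161 with an estimated correlation. Matrix proteases rose in 6 of 17 (10 adjusted over the list alone), with Ctsk at 1.45 and an adjusted p = 0.273 with an estimated correlation.

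Among the smaller shifts at day 2, RAS and ERK output genes rose in 8 of 16 and fell in 1 (9 and 2 adjusted over the list alone), with the EGF receptor ligand Ereg at 2.05 and an adjusted p = 0.248 with an estimated correlation. Inflammasome and pattern recognition genes rose in 7 of 20 and fell in 1 (10 and 1 adjusted over the list alone), with Cd14 at 1.77 and an adjusted p = 0.439 with an estimated correlation. Monocyte and recruited macrophage markers rose in 8 of 19 and fell in 2 (9 and 4 adjusted over the list alone). Interferon response genes rose in 4 of 21 (8 adjusted over the list alone), with Ifit3 at 0.87. Both lists had an adjusted p = 0.457 with an estimated correlation. Type 2 and alternative activation genes rose in 4 of 16 (4 adjusted over the list alone), with Ccl8 at 0.83 and an adjusted p = 0.427 with an estimated correlation. Club cell genes fell in 5 of 12 (7 lower and 1 higher adjusted over the list alone), with Scgb3a2 at -0.67, Cyp2f2 at -0.34 and an adjusted p = 0.285 with an estimated correlation. Ciliated cell genes fell in 5 of 15 (9 adjusted over the list alone), with an adjusted p = 0.318 with an estimated correlation. Endothelial genes fell in 4 of 19 (6 adjusted over the list alone), with Aplnr at -0.95 and an adjusted p = 0.407 with an estimated correlation. Genes of tissue that could be dissected along with the lung moved too: heart muscle genes fell in 8 of 12 (12 adjusted over the list alone, median -0.76), with Actc1 at -1.09 and an adjusted p = 0.273 with an estimated correlation. Fat genes fell in 1 of 9 (5 adjusted over the list alone), with an adjusted p = 0.399 with an estimated correlation. Mast cell, basophil and eosinophil markers fell in 3 of 14 (3 adjusted over the list alone), with Cpa3 at -0.68 and an adjusted p = 0.299 with an estimated correlation. This call was also lost with quantile normalization (0.0789), with cyclic loess (0.0925) and without BLT1+/+ CS day 2 replicate 2 (0.0646).

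The remaining 18 lists were not called at day 2. Neutrophil markers had 3 of 22 higher (5 adjusted over the list alone, adjusted p = 0.232), with Cd177 at 0.66 and Il1r2 at 1.52, and the leukotriene and prostanoid pathway 3 higher and 1 lower of 21 (3 and 1, adjusted p = 0.538). Single neutrophil genes were far higher in the day 2 than in the day 60 PBS pools, as given below. Alveolar macrophage markers had 3 higher and 1 lower of 14 (4 and 4 adjusted over the list alone, adjusted p = 0.634). Plasma cell markers had 1 each way of 9 (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.0718), lymphoid aggregate genes 4 higher and 3 lower of 13 (5 and 4, adjusted p = 0.811). Complement had 3 higher and 1 lower of 13 (4 and 1 adjusted over the list alone, adjusted p = 0.0718), with Cfb at 1.53 and C3ar1 at 1.23. Lysosome and lipid-laden macrophage genes had 6 higher and 4 lower of 15 (7 and 4 adjusted over the list alone, adjusted p = 0.135), with Gpnmb at 1.22. Alveolar type 2 genes had 2 higher and 4 lower of 17 (adjusted p = 0.231) and alveolar type 1 genes 1 each way of 11 (adjusted p = 0.552), with the same counts adjusted over the list alone. Immune checkpoint genes had 1 of 15 higher (adjusted p = 0.0804), thymus genes 2 of 9 lower (adjusted p = 0.0712), skeletal muscle genes 1 of 11 lower (adjusted p = 0.588), thyroid genes 1 of 5 higher (adjusted p = 0.864; Slc26a4 at 1.74), and circadian clock genes 2 higher and 1 lower of 13 (adjusted p = 0.787), each with the same counts adjusted over the list alone. Immediate early genes had 4 of 15 higher (4 higher and 2 lower adjusted over the list alone, adjusted p = 0.234). Squamous (adjusted p = 0.538), red blood cell (0.235) and sex-linked genes (0.898) had 0 by limma at either level. For neutrophil markers (median -0.00, mean 0.28), lymphoid aggregate genes (-0.02 and 0.07) and thyroid genes (-0.15 and 0.20), the median and the mean differed in sign.

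**Figure D1:**
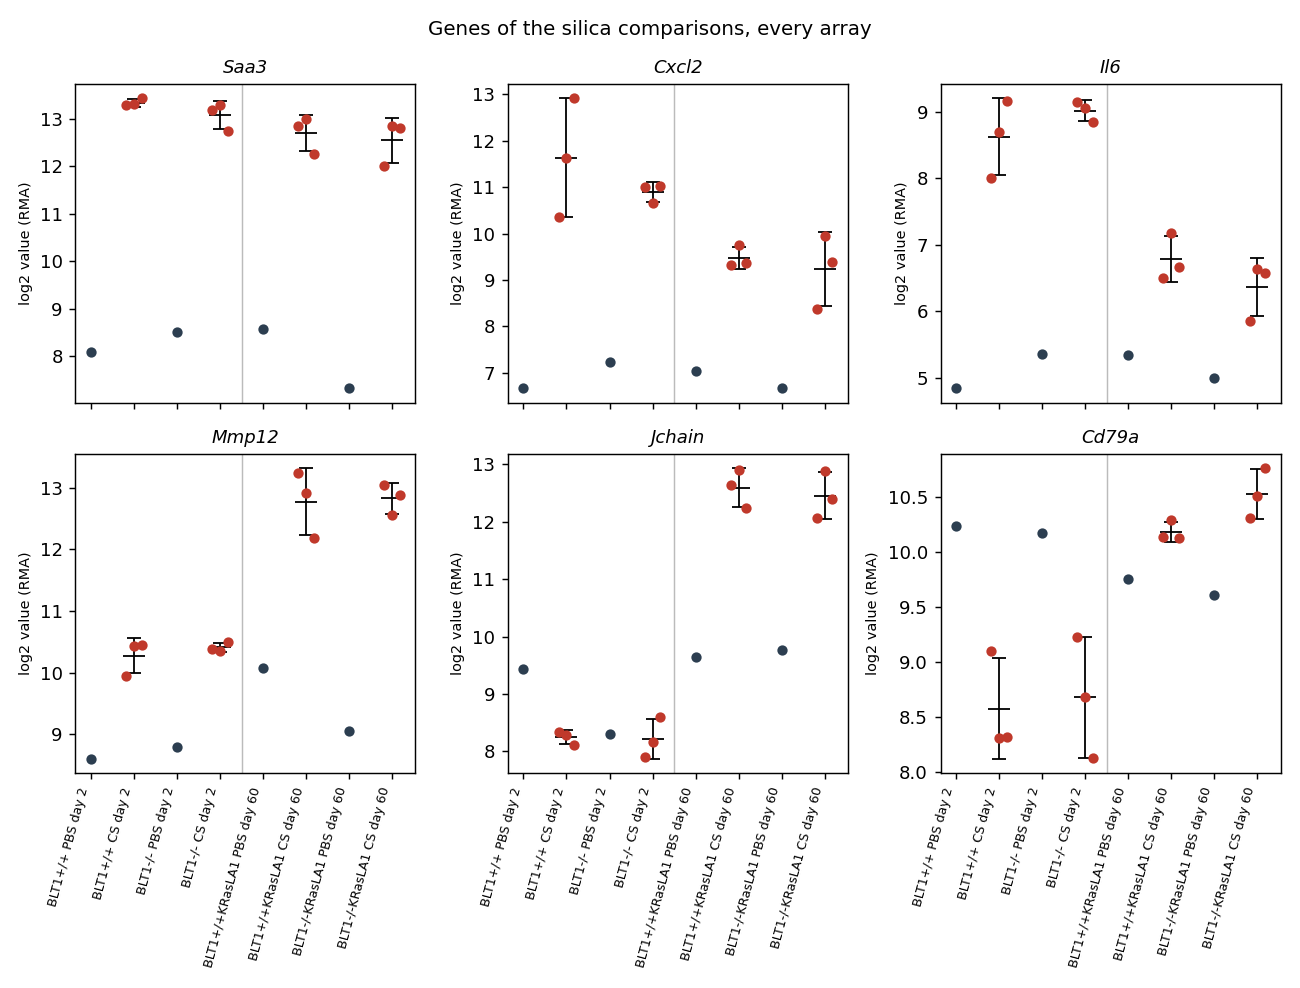
Log2 expression (vertical axis) of Saa3, Cxcl2, Il6, Mmp12, Jchain and Cd79a in the 8 groups (horizontal axis), with PBS pools as dark points, CS lungs as red points and bars for the mean ± SD of the CS lungs. These 6 genes were picked after their values were seen. Saa3 was above its PBS pool in every CS lung, Il6 rose by 3.73 at day 2 and 1.41 at day 60, and Cd79a fell by 1.58 at day 2.

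Each BLT1 genotype was also set against its own PBS pool at day 2. In BLT1+/+ lungs 170 genes rose and 62 fell, led by Saa3 (5.25 ± 0.31, 38.1-fold), Cxcl2 (4.96 ± 0.69, 31.2-fold), Ccl3 (4.15 ± 0.45, 17.8-fold), Il6 (3.79 ± 0.38) and the itaconate enzyme Acod1 (3.73 ± 0.58). Slc7a11 (3.32 ± 0.48), Ly6i (3.25 ± 0.36) and Tnf (2.21 ± 0.39, adjusted p = 0.0189) rose too, and Ms4a1 fell by 1.69 ± 0.30. In BLT1-/- lungs 1035 genes rose and 280 fell. Saa3 (4.56 ± 0.31, 23.6-fold), Il6 (3.67 ± 0.38, 12.7-fold), Cxcl2 (3.66 ± 0.69, 12.6-fold), Ccl3 (3.56), Timp1, Tnip3 (3.11), Tnc (3.04) and Ccl2 (3.01) led the rises, and Igfbp3 (-1.78 ± 0.27), Chad (-1.61) and Ppbp (-1.60) the falls. All of these had the same sign in 3 of 3 lungs. Tnf was at 0.64 ± 0.39 in BLT1-/- lungs (3 of 3, adjusted p = 0.331). All 25 cell cycle genes rose in BLT1-/- lungs (25 adjusted over the list alone, median 1.55, adjusted p = 0.266 with an estimated correlation). In BLT1+/+ lungs 9 of 25 rose (25 adjusted over the list alone, median 1.18, adjusted p = 0.138 with an estimated correlation). B cell markers fell in 6 of 15 in BLT1+/+ lungs (12 adjusted over the list alone, adjusted p = 0.0981 with an estimated correlation) and in 8 of 15 in BLT1-/- lungs (11 adjusted over the list alone, adjusted p = 0.285 with an estimated correlation). The genotypes shared 152 rises and 52 falls, where independent lists would share 8.83 and 0.871, and no gene was called in opposite directions. Across genes, which are not independent replicates, their log2 fold changes had r = 0.687 and rho = 0.425. The counts turned on single lungs: BLT1+/+ lungs gave 685, 65 and 77 genes without replicate 1, 2 and 3, where Ms4a1 (-1.66, adjusted p = 0.0680) and Tnf (2.22, adjusted p = 0.0650) were lost without replicate 2, and BLT1-/- lungs gave 829 without replicate 2 and 697 without replicate 3. With the day 2 replicate block the counts were 749 and 2345, with errors that are too small, with the 8 day 2 arrays alone 93 and 425, and against the pool of the other genotype, an alternative chosen after seeing the data, BLT1+/+ lungs gave 396, with Tnf lost (1.55, adjusted p = 0.0601).

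At day 60, in lungs with the KRasLA1 allele, silica raised acute phase, macrophage, T cell and plasma cell genes, averaged over both BLT1 genotypes. Saa3 again rose most, by 4.68 ± 0.22 (25.6-fold, adjusted p = 2.07e-07), followed by Ly6i (16.7-fold, 4.06 ± 0.26), the eosinophil-associated ribonuclease Rnase2a (10.8-fold, 3.44 ± 0.57), the macrophage elastase Mmp12 (9.43-fold, 3.24 ± 0.21) and Acod1 (9.29-fold, 3.22 ± 0.41). Ccl3 rose 7.90-fold (2.98 ± 0.32), Fbp1 7.64-fold (2.93 ± 0.63) and Jchain, the joining chain of secreted IgA and IgM, 7.08-fold (2.82 ± 0.21). The falls were smaller: Fabp1 changed by -1.23 ± 0.26, Sult1d1 by -1.20, Bex2 by -1.02, Scgb1c1 by -0.99 ± 0.10, Slc5a8 by -0.91, the antioxidant lactonase Pon1 by -0.90 ± 0.11 and the smooth muscle protein Cnn1 by -0.89. Of the panel, Cxcl2 (2.51), Ccl2 (2.21, 4.61-fold), Il6 (1.41), Cxcl5 (1.24), Retnla (1.17), Mmp9 (1.04), Lcn2 (1.02) and Chil3 (0.93) rose. Il1b (adjusted p = 0.0231), S100a8 (1.46, adjusted p = 0.0347) and Tnf (1.06, adjusted p = 0.0483) rose as well. S100a8, Mmp9 and Retnla were lower in the day 60 than in the day 2 PBS pools, as given below. Their rises are thus set against a lower control than at day 2. Scgb1c1 was higher in the day 60 than in the day 2 PBS pools, as given below, so its fall is set against a higher control. Each gene named so far had the same sign in 6 of 6 lungs. Arg1 was at 1.21 (adjusted p = 0.190, 6 of 6 lungs), Cxcl1 at 0.61 (adjusted p = 0.0511, 6 of 6 lungs) and S100a9 at 1.02 (adjusted p = 0.167, 5 of 6 lungs). Mmp8 (0.74), Alox5ap (0.37), Alox5 (-0.02) and Lta4h (0.05) did not pass either. In all, 667 genes were higher and 135 lower, 394 and 25 of them by at least 1.5-fold. Array weights gave 1729 genes, and additive fits of the day 60 arrays gave 171 without the BLT1+/+ pool and 58 without the BLT1-/- pool. Of the genes called in this paragraph, Saa3, Ly6i, Mmp12, Acod1, Ccl3, Jchain, Scgb1c1, Pon1 and Lcn2 passed in both of those fits, Cxcl2 (2.43, adjusted p = 0.0865), Il1b (0.88, 0.193) and Retnla (0.64, 0.208) were lost without the BLT1-/- pool, and the others were lost without either, Rnase2a at 4.41 (0.0768) and 2.46 (0.370).

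Chemokines rose in 15 of 23 at day 60 (19 adjusted over the list alone, median 1.10), among them Ccl9 (2.04) and Ccl22 (1.18). Monocyte and recruited macrophage markers rose in 12 of 19 (14 higher and 1 lower adjusted over the list alone), with the complement component C1qb at 0.98. Lysosome and lipid-laden macrophage genes rose in 8 of 15 and fell in 1 (11 and 1 adjusted over the list alone), with Gpnmb at 1.92, Cd68 at 1.04 and the acid lipase Lipa at 0.63. Alveolar macrophage markers rose in 5 of 14 and fell in 1 (7 and 2 adjusted over the list alone), with Itgax at 1.05 and Atp6v0d2 at 0.99. T cell markers rose in 12 of 20 (17 adjusted over the list alone, median 0.56), with Il7r at 1.40, Ctla4 at 1.12, Icos at 1.07 and Cd3g at 1.03. Cd3g, and the T cell list with the preset correlation, were lower in the day 60 than in the day 2 PBS pools, as given below. Their rise is thus set against a lower control than at day 2. Plasma cell markers rose in 7 of 9 (7 adjusted over the list alone), with Mzb1 at 1.26 and Irf4 at 0.97. Immune checkpoint and suppressive genes rose in 9 of 15 (10 adjusted over the list alone), with Pdcd1lg2 at 1.29 and Cd274 (PD-L1) at 0.91. Matrix proteases rose in 12 of 17 (12 adjusted over the list alone), with Ctsk at 1.85, acute phase proteins in 8 of 12 (9) and complement in 8 of 13 (9), with Cfb at 1.65 and C3ar1 at 1.61. Type 2 and alternative activation genes rose in 7 of 16 (11 adjusted over the list alone), with Ccl8 at 1.18. Inflammasome and pattern recognition genes rose in 9 of 20 and fell in 1 (16 and 1 adjusted over the list alone), with Msr1 at 1.60 and Clec7a at 0.96. Dendritic cell and MHC class II genes rose in 7 of 19 and fell in 1 (14 and 1 adjusted over the list alone), with Cd86 at 0.87. Cytokines rose in 9 of 22 and fell in 1 (10 and 1 adjusted over the list alone), with Il1a at 1.83. Extracellular matrix genes rose in 7 of 21 and fell in 1 (9 and 1 adjusted over the list alone), with Timp1 at 1.79. These 15 lists, and the sex-linked genes, kept their camera call with an estimated correlation, with adjusted p from 0.0326 to 0.0352.

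Other lists were called at day 60 with the preset correlation and not with an estimated one, and fry called some of them. Interferon response genes rose in 13 of 21 (21 adjusted over the list alone, median 0.84, adjusted p = 0.0783 with an estimated correlation), with the regulator Irf7 at 1.91, Zbp1 at 1.40 and Oas3 at 1.25. Neutrophil markers rose in 6 of 22 (11 adjusted over the list alone, adjusted p = 0.0698 with an estimated correlation), with Clec4e at 2.69 and Cd177 at 1.94. Single neutrophil genes were far lower in the day 60 than in the day 2 PBS pools, so this rise is set against a lower control. B cell markers rose in 4 of 15 (11 adjusted over the list alone, adjusted p = 0.0868 with an estimated correlation), with Fcer2a at 1.35 and Cd72 at 1.19. The leukotriene and prostanoid pathway had 5 of 21 higher (6 adjusted over the list alone, adjusted p = 0.0512 with an estimated correlation), with Ptgir at 1.35 and Tbxas1 at 0.83. Lymphoid aggregate genes had 3 of 13 higher (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.0687 with an estimated correlation), with Ccl19 at 0.90. Cell cycle genes had 2 of 25 higher (19 adjusted over the list alone, median 0.59, adjusted p = 0.166 with an estimated correlation). Smaller upward calls were NK markers with 0 of 13 by limma (1 adjusted over the list alone, adjusted p = 0.340 with an estimated correlation), which was lost without BLT1+/+KRasLA1 CS replicate 3 (0.0591), and thymus genes with 2 of 9 (2 adjusted over the list alone, adjusted p = 0.258 with an estimated correlation), lost without BLT1-/-KRasLA1 CS replicate 1 (0.0938). Adenoma and epithelial plasticity genes had 3 of 19 higher (3 adjusted over the list alone, adjusted p = 0.264 with an estimated correlation), with Slc5a1 at 1.07. Oxidative stress genes had 2 higher and 1 lower of 16 (4 and 3 adjusted over the list alone, adjusted p = 0.544 with an estimated correlation), a call lost without either replicate 2 (0.102 and 0.184), centred (0.0529) and with cyclic loess (0.0825). Alveolar type 1 genes had 2 of 11 lower (6 adjusted over the list alone, adjusted p = 0.109 with an estimated correlation), and club cell genes 3 of 12 lower (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.195 with an estimated correlation). Endothelial genes had 0 of 19 by limma at either level (adjusted p = 0.378 with an estimated correlation) and circadian clock genes 1 of 13 lower (2 adjusted over the list alone, adjusted p = 0.181 with an estimated correlation), with Per1 at -0.58.

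Genes of neighbouring tissue and of sex were also tested at day 60. Heart muscle genes had 0 of 12 by limma (8 lower adjusted over the list alone, median -0.56, adjusted p = 0.181 with an estimated correlation), and fat genes 0 of 9 (1 lower adjusted over the list alone, adjusted p = 0.405 with an estimated correlation), a call lost without BLT1-/-KRasLA1 CS replicate 1 (0.0718) or BLT1+/+KRasLA1 CS replicate 2 (0.0595). Sex-linked genes had 0 of 4 past the threshold (3 lower adjusted over the list alone, median -2.48), with Eif2s3y at -3.88 (adjusted p = 0.0507). Not called were alveolar type 2 genes with 2 of 17 higher (2 adjusted over the list alone, adjusted p = 0.152; Sftpd at 0.32), mast cell, basophil and eosinophil markers with 1 of 14 higher (2 adjusted over the list alone, adjusted p = 0.458), thyroid genes with 1 of 5 (1 adjusted over the list alone, adjusted p = 0.570; Slc26a4 at 2.42) and immediate early genes with 2 of 15 (2 adjusted over the list alone, adjusted p = 0.348; Egr2 at 0.66). Ciliated cell (adjusted p = 0.321), RAS and ERK output (0.925), skeletal muscle (0.321), squamous (0.136) and red blood cell genes (0.479) had 0 by limma at either level. Median and mean differed in sign for mast cell markers (-0.06 and 0.05), thyroid genes (-0.15 and 0.38) and RAS and ERK output (0.00 and -0.03). The weakest gene calls of day 60 were those of Tnf, Il1b, S100a8, Bex2 and Cnn1. Without BLT1-/-KRasLA1 CS replicate 2 they gave 1.00, 1.43, 1.30, -0.96 and -0.91 (adjusted p from 0.0509 to 0.0973). S100a8 was also lost without BLT1-/-KRasLA1 CS replicate 3 (1.47, 0.0618), Cnn1 without that lung (-0.84, 0.0786) and without BLT1+/+KRasLA1 CS replicate 1 (-0.93, 0.0523), and Tnf without any of the other 5 lungs but BLT1-/-KRasLA1 CS replicate 1 (0.98 to 1.08, adjusted p from 0.0564 to 0.0975), with quantile normalization (0.0610), centring (0.0520) and loess (0.0574). With the male share as a covariate, chosen after seeing the data, the calls of Fbp1 (2.23), Fabp1 (-1.20), Bex2 (-0.97), Ces1f (-0.98), Slc5a8 (-0.89), Il1b (1.29), S100a8 (1.08), Tnf (1.14), Irf7 (1.94) and Oas3 (1.24) were lost, with adjusted p from 0.0571 to 0.198.

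**Figure D2:**
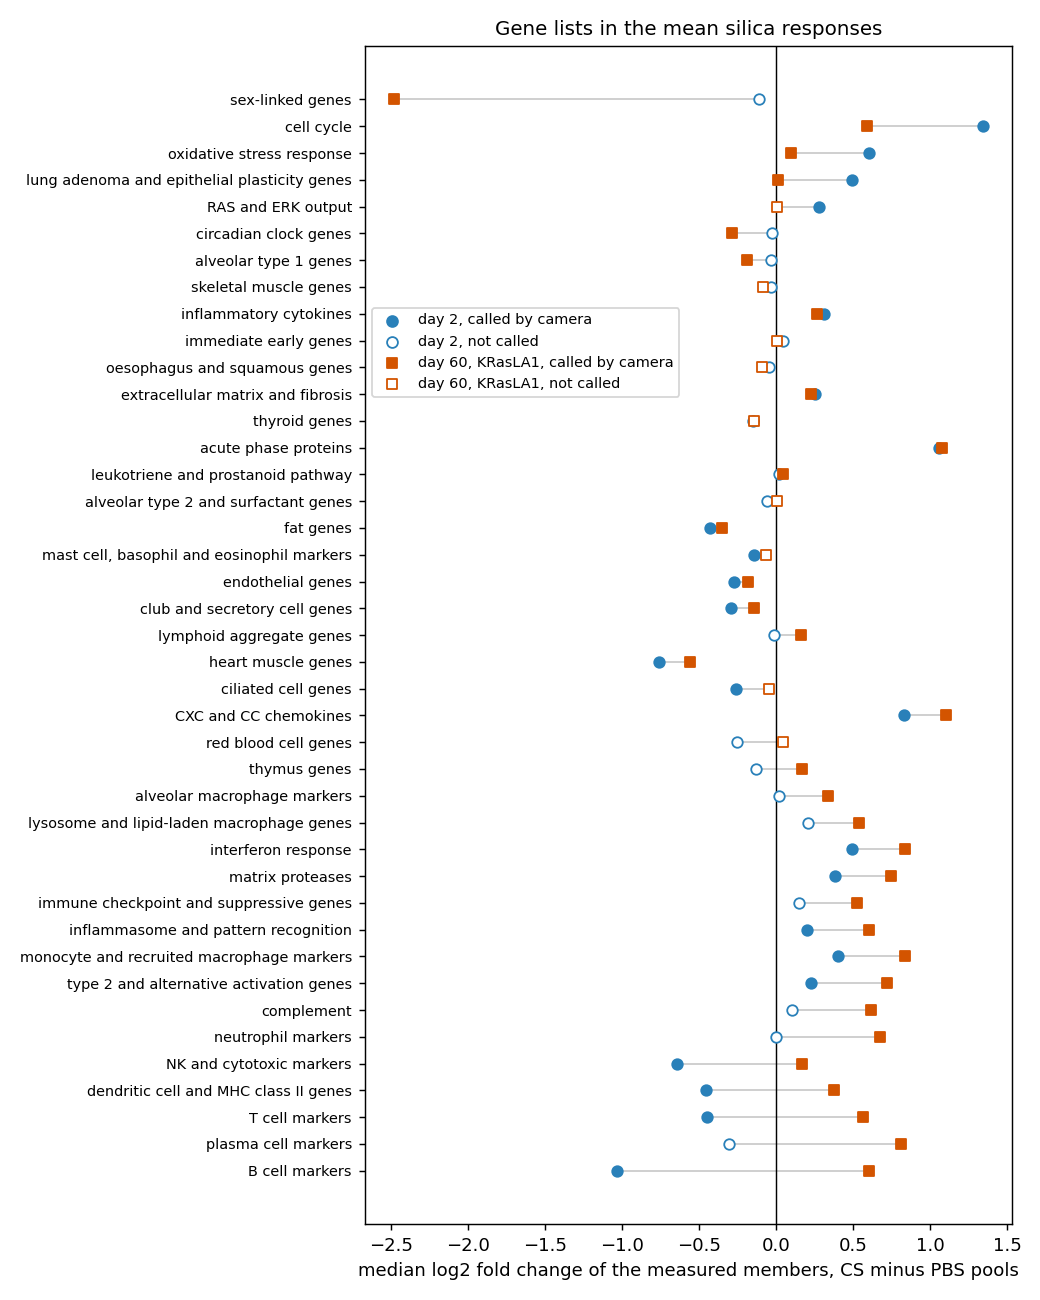
Median log2 fold change after silica (horizontal axis) of each of the 41 gene lists (vertical axis), averaged over BLT1 genotypes, with day 2 as blue circles and day 60 as orange squares. Filled points were called by camera with the preset correlation and open points were not. B cell markers lie at -1.03 on day 2 and 0.60 on day 60, and cell cycle genes at 1.34 and 0.59.

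Against their own pools at day 60, 137 genes rose and 15 fell in BLT1+/+KRasLA1 lungs, and 220 rose and 14 fell in BLT1-/-KRasLA1 lungs. BLT1+/+KRasLA1 lungs were led by Saa3 (4.14 ± 0.31, 17.6-fold), Ly6i (3.95 ± 0.36, 15.4-fold), Acod1 (3.52 ± 0.58), Jchain (2.96 ± 0.30) and Mmp12 (2.70 ± 0.30), with Scgb1c1 and Lypd2 (-1.01 ± 0.19) at the other end. BLT1-/-KRasLA1 lungs were led by Saa3 (5.22 ± 0.31, 37.4-fold), Rnase2a (4.41 ± 0.81, 21.3-fold), Ly6i (4.18 ± 0.36, 18.1-fold), Mmp12 (3.77 ± 0.30, 13.7-fold) and Ccl3 (3.35), and Retnla, a gene of alternative macrophage activation, rose by 1.70 ± 0.16 (adjusted p = 0.000151). All had the same sign in 3 of 3 lungs. Chemokines rose in 6 of 23 in BLT1+/+KRasLA1 lungs (16 adjusted over the list alone, adjusted p = 0.0619 with an estimated correlation) and in 4 of 23 in BLT1-/-KRasLA1 lungs (19 adjusted over the list alone), where the call held with an estimated correlation (adjusted p = 0.0318). T cell markers rose in 3 of 20 (10 adjusted over the list alone, adjusted p = 0.0728 with an estimated correlation) and 6 of 20 (16 adjusted over the list alone, adjusted p = 0.0318 with an estimated correlation). The genotypes shared 104 rises and 4 falls, against 1.51 and 0.0105 for independent lists, with none opposite, and r = 0.711 and rho = 0.392 across genes. Without replicate 1, 2 and 3 BLT1+/+KRasLA1 lungs gave 43, 62 and 477 genes and BLT1-/-KRasLA1 lungs 432, 112 and 69. The calls of Lypd2 without replicate 1 (-1.06, adjusted p = 0.0559) or 2 (-1.02, adjusted p = 0.0731), of Acod1 without replicate 1 (3.45, adjusted p = 0.0532) and of Rnase2a without replicate 3 (4.08, adjusted p = 0.0744) were lost. Array weights gave 676 and 876 genes, the 8 day 60 arrays 59 for BLT1+/+KRasLA1, the male share, chosen after seeing the data, 246 for BLT1+/+KRasLA1, and centring 127 for BLT1-/-KRasLA1.

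The day 60 and day 2 mean responses were then tested against each other, a comparison in which time and KRasLA1 change together. Lymphocyte genes responded more positively at day 60: Jchain differed by 3.46 ± 0.30 (adjusted p = 0.000232), Ms4a1 by 2.30 ± 0.30, Cd79a by 2.25, Ly6d by 2.06 and Gimap3 by 2.00. H2-M2 (2.77 ± 0.56), the goblet cell product Clca1 (2.75 ± 0.63, adjusted p = 0.0386), Awat1 (2.30), Mmp12 (1.59) and Mmp9 (1.22) were also higher. Each of these values also holds the difference between the PBS pools of the days. Mmp9 was lower in the day 60 pools, as given below, so its value does not show a higher level in the day 60 CS lungs. Lower were the keratinocyte envelope gene Sprr1a by -2.69 ± 0.50, Il6 by -2.32 ± 0.38 (adjusted p = 0.00583), Ereg by -2.30 ± 0.56 (adjusted p = 0.0490), Tnc by -1.86, the metallothionein Mt2 by -1.64, S100a14 by -1.61, Cxcl13 by -1.60 and the hyaluronan synthase Has2 by -1.59. Saa3 (-0.23, adjusted p = 0.878), Cxcl2 (-1.80, adjusted p = 0.240) and S100a8 (1.59, adjusted p = 0.140) did not differ past the threshold. B cell markers were higher in 13 of 15 (15 adjusted over the list alone, median 1.60), T cell markers in 17 of 20 (20, median 1.02), NK markers in 8 of 13 (12, median 0.92) and plasma cell markers in 6 of 9 (7 higher and 1 lower adjusted over the list alone, median 1.40). All held with an estimated correlation (adjusted p = 0.045 each), as did dendritic cell and MHC class II genes with 12 of 19 (15 adjusted over the list alone, adjusted p = 0.0350). T cell markers were called lower in the day 60 pools with the preset correlation, as given below, so their value also holds that difference. Cell cycle genes were lower in 3 of 25 (22 adjusted over the list alone, median -0.75, adjusted p = 0.239 with an estimated correlation), and oxidative stress genes in 5 of 16 (8 lower and 1 higher adjusted over the list alone, adjusted p = 0.227 with an estimated correlation). Heart muscle genes were not called here. In all 338 genes were higher and 131 lower. The mean responses shared 213 rises and 48 falls (53.6 and 5.90 for independent lists), 68 genes were called in opposite directions, and r was 0.431 and rho 0.357 across genes. Without BLT1-/-KRasLA1 CS replicate 3 there were 312 genes, without BLT1+/+ CS day 2 replicate 1 there were 716, and with the day 2 replicate block 977. Has2 and Ereg were lost under each of the 3 other scalings and Cxcl13 under 2 of them. Each single lung but BLT1+/+ CS day 2 replicate 1 ended at least 1 of the calls of Clca1 (2.63 to 2.80 where lost), Ereg (-2.17 to -2.38), Has2 (-1.49 to -1.61), Cxcl13 (-1.51 to -1.64), S100a14 (-1.51 to -1.60) and Mmp9 (1.17 to 1.23), with adjusted p from 0.0526 to 0.0921.

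The PBS pools of the KRasLA1 mice at day 60 were compared with those of the mice without the allele at day 2, 2 pools against 2, since they are the background of every response. Single neutrophil genes were far lower in the day 60 pools. Ly6g was lower by -3.32 ± 0.46 (9.99-fold), Retnlg by -3.28 ± 0.44, S100a8 by -3.05 ± 0.43 (8.27-fold), the receptor Cxcr2 by -2.48, S100a9 by -2.45 and the granule protein Ngp by -2.06 ± 0.21. Slfn1 (-1.73), Ms4a4a (-1.61), Mmp9 (-1.38) and Retnla (-1.02) were lower too. Cd200r4 (1.40 ± 0.23), the clock repressor Bhlhe41 (1.34 ± 0.17), Atp6v0d2 (1.03), Efcab10 (0.97), Cd209f (0.94), the protease Ctsk (0.93), Mcoln3 (0.90) and Scgb1c1 (0.83) were higher. Neutrophil markers were lower in 7 of 22 (13 adjusted over the list alone, median -1.26, adjusted p = 0.0669 with an estimated correlation), and alveolar macrophage markers higher in 2 of 14 (8 adjusted over the list alone, adjusted p = 0.0340 with an estimated correlation). Circadian clock genes had 1 higher and 1 lower of 13 (7 and 2 adjusted over the list alone, median 0.43, adjusted p = 0.394 with an estimated correlation), with Arntl at -1.22, and sex-linked genes 0 of 4 (3 higher adjusted over the list alone, adjusted p = 0.0803 with an estimated correlation). In all 33 genes were higher and 46 lower, a split that became 33 and 28 after centring. The spread behind this test comes from the CS lungs. Without BLT1+/+ CS day 2 replicate 2 it gave 38 genes, without BLT1-/- CS day 2 replicate 1 or BLT1-/-KRasLA1 CS replicate 2 it gave 52 each, and without a variance trend 44. With the values themselves unchanged, S100a9, Cxcr2, Mmp9, Ms4a4a and Cd209f were lost without BLT1+/+ CS day 2 replicate 2 (adjusted p of S100a9 0.0562), Cxcr2 also without BLT1-/- CS day 2 replicate 1 (0.0506), and Slfn1, Ctsk and Efcab10 without 4 or more single lungs.

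Few genes separated BLT1-/- from BLT1+/+ lungs after silica. At day 2 the eosinophil-associated ribonuclease Ear6 (probe set 10414590) was lower by -1.26 ± 0.18 in BLT1-/- lungs (2.40-fold, adjusted p = 0.0351), the neutrophil granule gene Ngp by -1.22 ± 0.17 (adjusted p = 0.0351), the phospholipase Ddhd1 by -0.66 ± 0.07 (adjusted p = 0.00409) and Tmem260 by -0.60 ± 0.07 (adjusted p = 0.00868). No gene was higher (0 by limma), while 1735 genes had an unadjusted p under 0.05. At day 60 Rnase2b (probe set 10414551), another ribonuclease of that family, was lower by -1.92 ± 0.24 (3.79-fold, adjusted p = 0.00583), Ear6 by -1.78 ± 0.18, the synaptotagmin Syt15 by -1.05 ± 0.12, Ddhd1 by -0.58 ± 0.07 and Tmem260 by -0.48 ± 0.07. Rnase1 (0.96 ± 0.14), Klhl33 (0.83 ± 0.10) and Lrrc18 (0.65 ± 0.10) were higher, and 810 genes had an unadjusted p under 0.05. For each gene called, all 3 lungs of one genotype lay beyond all 3 of the other, a separation that chance gives to 10% of genes at 3 against 3. The days shared Ear6, Ddhd1 and Tmem260, but fold changes over all genes had r = -0.0547 and rho = -0.123. Ear6, Rnase2a and Rnase2b belong to a family of near-identical genes, and their probe sets may read more than 1 of them. All of these genes but Ngp lie on the chromosome of Ltb4r1, and without the genes of that chromosome, an alternative chosen after seeing the data, both counts were 0 by limma. Ngp kept its value of -1.22 there and lost its call only through the adjustment over the remaining genes (adjusted p = 0.130). The PBS pools of the genotypes differed in the same direction as the CS lungs for Ddhd1 (-0.66 at day 2 and -0.58 at day 60), Tmem260 (-0.53 and -0.33), Syt15 (-0.57 and -0.75), Klhl33 (0.80 and 0.90), Lrrc18 (0.43 and 0.56) and Rnase1 (0.95 and 0.38), with 1 array each. The pools differed far less than the CS lungs for Ear6 (-0.15 and -0.53) and Rnase2b (-0.07 and -0.22). Rnase2b lay between 5.96 and 6.18 in the pools, below the lower quartile of each pool's array, so a difference there could be hidden near the floor.

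Of the panel, Tnf was at -0.91 ± 0.28 between BLT1 genotypes at day 2 (adjusted p = 0.322), Cxcl2 at -0.74 ± 0.49, Saa3 at -0.26 ± 0.22, Il6 at 0.40 and S100a8 at -0.32 ± 0.36. At day 60 Saa3 was at -0.16 ± 0.22, Arg1 at -0.70 and Il1b at 0.03 ± 0.34. None passed. In camera, 3 lists were higher and 10 lower without BLT1 at day 2, and none held with an estimated correlation. Interferon response genes were lower in 0 of 21 by limma (6 adjusted over the list alone, median -0.51, adjusted p = 0.494 with an estimated correlation) and neutrophil markers in 1 of 22 (3 adjusted over the list alone, median -0.29, adjusted p = 0.494 with an estimated correlation). Ciliated cell genes were lower in 0 of 15 (9 adjusted over the list alone, adjusted p = 0.346 with an estimated correlation), with Sec14l3 at -0.38, and club cell genes in 0 of 12 (7 adjusted over the list alone, adjusted p = 0.320 with an estimated correlation), with Cbr2 at -0.23. Extracellular matrix genes (median 0.21, 2 higher adjusted over the list alone) and RAS and ERK output (median 0.21, 5 higher adjusted over the list alone) had an adjusted p = 0.117 each with an estimated correlation, with Col1a1 at 0.48 and Ccnd1 at 0.36. At day 60, 5 lists were higher and 8 lower, again with none held. T cell markers had a median of 0.27 (3 higher adjusted over the list alone, adjusted p = 0.392 with an estimated correlation). Leaving out single lungs gave 1 to 6 genes at day 2 and 1 to 7 at day 60. At day 2 there was 1 gene without BLT1-/- replicate 1 or 2 and 2 without BLT1+/+ replicate 2 or 3, with Ear6 from -1.11 to -1.25 and Ngp from -1.08 to -1.22 (adjusted p from 0.0952 to 0.284). At day 60 there was 1 without BLT1-/-KRasLA1 replicate 2, where Ear6 alone stayed, and 5 without its replicate 3. Tmem260 was lost at day 2 without BLT1-/- replicate 1 or 2 (-0.61, adjusted p = 0.0594 and 0.0634), and at day 60 Tmem260 was lost without any of the 6 lungs, Lrrc18 without 5 and Rnase1 without 4 (adjusted p from 0.0865 to 0.219). The 8 arrays of day 2 gave 2 higher genes and 0 lower by limma, so all 4 calls were lost, those of day 60 gave 3 genes, and quantile normalization gave 1 higher and 5 lower at day 2. With the replicate block over the 12 CS arrays 2 genes passed at day 2, Ear6 and Ngp being lost (adjusted p = 0.127 each), with the block over all arrays 21, and Tmem260 was lost at day 60 (0.0725).

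**Figure D3:**
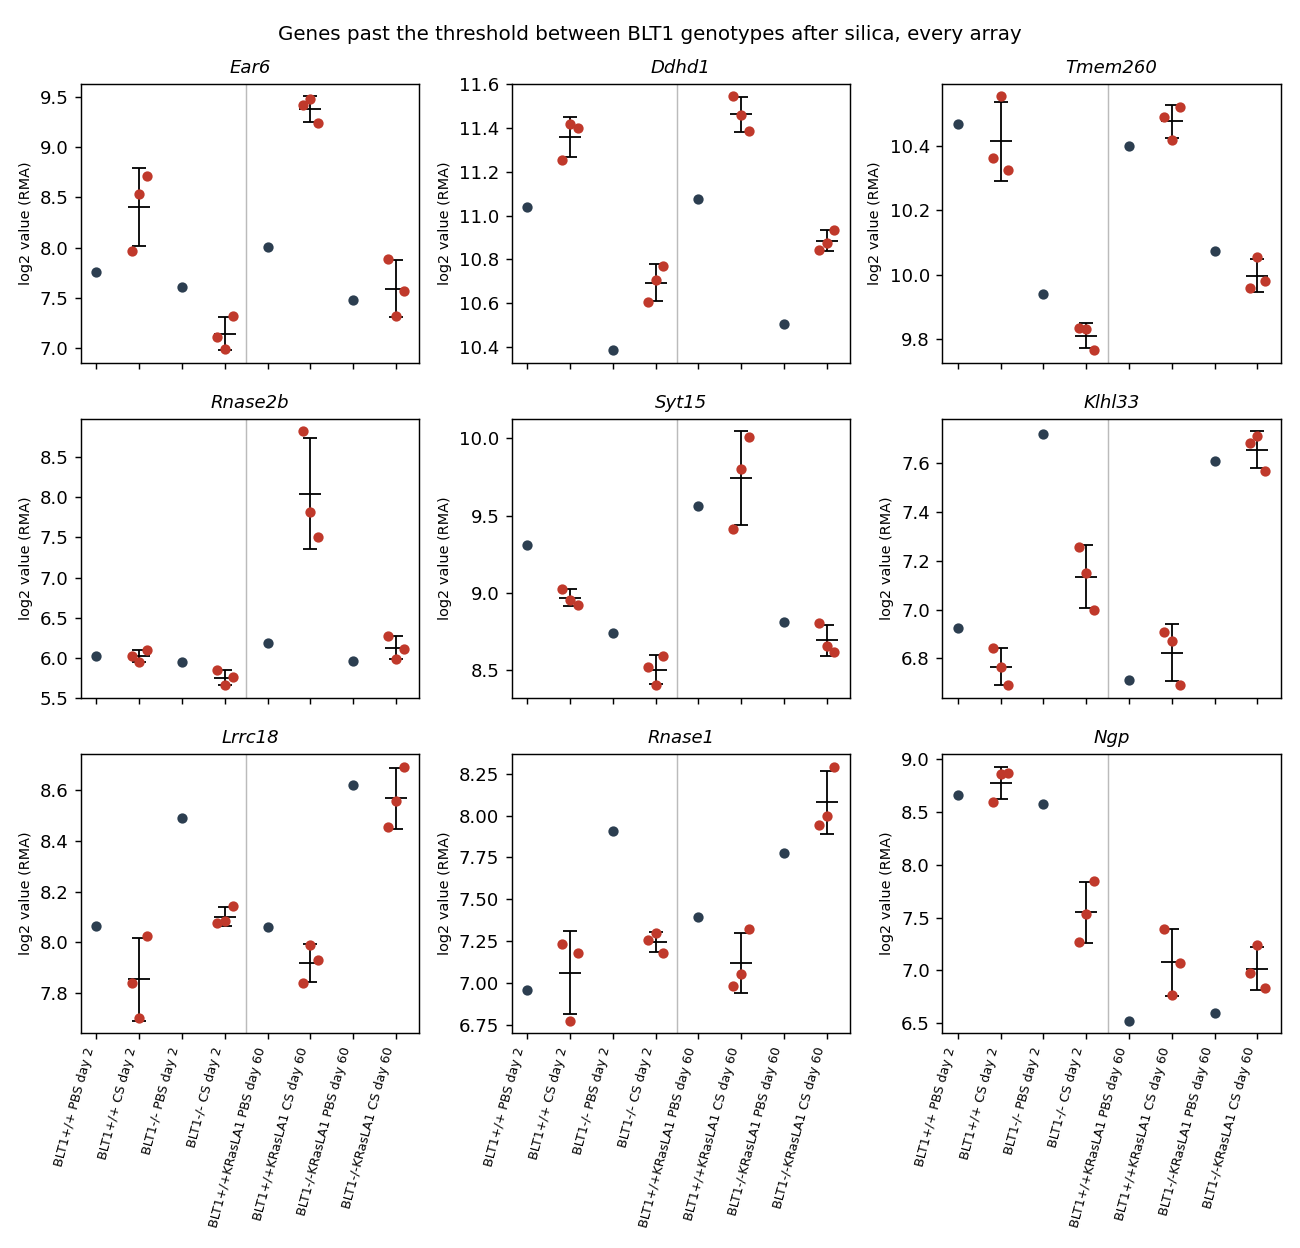
Log2 expression (vertical axis) of the 9 genes that passed the threshold between BLT1 genotypes after silica, in the 8 groups (horizontal axis), with PBS pools as dark points, CS lungs as red points and bars for the mean ± SD of the CS lungs. Ddhd1 is lower in BLT1-/- samples with and without silica, while the Ngp pools of day 2 differ by -0.08 and its CS lungs by -1.22.

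The interaction asked whether the silica response itself differed between BLT1 genotypes. By limma 0 genes passed at day 2, where 896 had an unadjusted p under 0.05, and 0 at day 60, where 396 did. The smallest p at day 2 were those of the zinc finger genes Zfp979 (1.32 ± 0.26), Zfp980 (0.85) and Zfp935 (0.74) and of the olfactory receptors Olfr710 (-0.81) and Olfr1489 (-1.13), all with an adjusted p = 0.820. Tnf, whose response was called in BLT1+/+ lungs alone, had an interaction of -1.57 ± 0.55 (unadjusted p = 0.0135, adjusted p = 0.820), Cxcl2 -1.31 ± 0.98 and Saa3 -0.69 ± 0.44. At day 60 the smallest p belonged to Med28 (-0.65), Retnla (1.06 ± 0.22, unadjusted p = 0.000299, adjusted p = 1.00), Dennd4a (0.55), Polr2f (-0.48) and Bmper (0.59), with Saa3 at 1.09 ± 0.44 and Mmp12 at 1.07 ± 0.43. Camera called 3 lists higher and 5 lower at day 2, among them neutrophil markers (median -0.67), interferon response (-0.47) and cell cycle (0.41), each with an adjusted p = 0.972 with an estimated correlation. It called 9 higher and 3 lower at day 60, among them immediate early genes (0.53, adjusted p = 0.352 with an estimated correlation) and NK markers (0.44, adjusted p = 0.621 with an estimated correlation). No count moved from 0 without any single lung. With the day 2 replicate block, whose errors are too small, circadian clock genes were called by camera with the preset correlation (adjusted p = 0.0391). At that correlation they were not called without the block. Without it and with an estimated correlation they had an adjusted p = 0.972. That value differs in both settings, so the pair does not measure the effect of the block.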

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

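The fit of probe sets without a single gene name was chosen only after the results of the named genes were seen; the other tests in this part were planned. The response to silica differed between day 60 in KRasLA1 lungs and day 2 in lungs without the allele for 469 genes, by the test of the difference itself, and time and KRasLA1 cannot be told apart in it. Higher at day 60 were the responses of Jchain (3.46), H2-M2 (2.77), Clca1 (2.75), Ms4a1 (2.30), Awat1 (2.30), Cd79a (2.25), Ly6d (2.06), Gimap3 (2.00), Mmp12 (1.59) and Mmp9 (1.22). Mmp9 was itself lower in the day 60 PBS pools, so its value does not show a higher level in the day 60 CS lungs. Lower were Sprr1a (-2.69), Il6 (-2.32), Ereg (-2.30), Tnc (-1.86), Mt2 (-1.64), S100a14 (-1.61), Cxcl13 (-1.60) and Has2 (-1.59). Gene lists that differed with an estimated correlation too were T cell markers (median 1.02), NK and cytotoxic markers (0.92), B cell markers (1.60), plasma cell markers (1.40) and dendritic cell and MHC class II genes (0.76). T cell markers were called lower in the day 60 PBS pools with the preset correlation, so their value also holds that difference. With the preset correlation camera called 27 lists in this difference, and it called 8 lists in the BLT1 by silica interaction at day 2 and 12 at day 60, where no gene passed. None of the interaction lists was called with an estimated correlation or with fry.

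Probe sets that the comparisons of named genes left out also passed the threshold, in both directions. Of 12146 probe sets without a gene symbol, 48 rose and 12 fell after silica at day 2, and 41 rose at day 60, with none lower. Of 1621 with several symbols, 26 rose and 2 fell at day 2, and 17 rose and 4 fell at day 60.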

How the results depend on the processing

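The male share, the other genotype's PBS pool, the removal of the chromosome of Ltb4r1 and the day 2 block over all arrays were chosen only after the results were seen; the other alternatives were planned. No scaling moved the median of all genes by over 0.1. Of the calls of named genes, counted over the alternatives that tested them, 8946 stayed and 1303 were lost. Of the list calls, counted likewise, 3725 stayed and 433 were lost. No called gene changed direction, and no list called in both settings did. A list that lost its call was counted as lost whatever its direction. In the main direction, 544 gene values and 140 list values passed only under an alternative. In the opposite direction 3 gene values did so. Neither tally holds fry or the 1.5-fold minimum. Lists were not tested in the additive fits or with the other genotype's PBS pool, so the list tally leaves these out. Lone PBS pools and the arms left with fewer lungs were assumed to vary like the other CS lungs. Signal over background limits the dim probe sets, for which no detection call was used. Except where fewer genes, arrays or lungs entered, the cause was not tested.

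Main counts of genes past the threshold were 232 (day 2, BLT1+/+), 1315 (day 2, BLT1-/-), 152 (day 60, BLT1+/+KRasLA1), 234 (day 60, BLT1-/-KRasLA1), 2473 and 802 (mean responses), 4 and 8 (BLT1 differences), 469 (difference between days) and 79 (PBS pools). A minimum of 1.5-fold left 755 for BLT1-/- at day 2 and 696 and 419 for the mean responses. Genes at or above the median level gave 7 and 3 for the BLT1 differences, and centring gave 127 for BLT1-/-KRasLA1. Without a variance trend there were 134 for BLT1+/+ at day 2, 101 for BLT1+/+KRasLA1, 2 for the day 2 BLT1 difference and 44 for the pools. Array weights, which ran from 0.318 to 2.20, gave 2647 for BLT1-/- at day 2, 676 and 876 for the day 60 genotypes, 1729 for the mean at day 60, 14 for the day 60 BLT1 difference, 875 for the difference between days and 335 for the pools. The 8 arrays of a day gave 93, 425 and 1589 for the day 2 responses, 2 for the day 2 BLT1 difference, 59 for BLT1+/+KRasLA1 and 3 for the day 60 BLT1 difference. Additive fits gave 426 and 171 for the mean responses without the BLT1+/+ pool, with 133 named calls lost, and 96 and 58 without the BLT1-/- pool, with 174 lost. The male share gave 246 for BLT1+/+KRasLA1, with Xist at -2.20 in BLT1-/-KRasLA1 lungs, opposite to its main direction. The other genotype's pool gave 396 for BLT1+/+ at day 2, and without the chromosome of Ltb4r1 both BLT1 differences gave 0 by limma, where Ngp, which lies elsewhere, kept its value (-1.22) and was lost only through the adjustment (0.130). Centring moved the pools from 33 higher and 46 lower to 33 and 28, and quantile normalization the day 2 BLT1 difference to 1 and 5. Of 251 list calls, 35 held with an estimated correlation and 112 with fry.

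With the replicate block over the 12 CS arrays the BLT1 difference gave 2 genes at day 2 and 7 at day 60. Ear6 and Ngp at day 2 and Tmem260 at day 60 were lost. Day 2 chemokines were called by camera with the preset correlation (adjusted p = 0.0493), which they were not in the main fit. Without the block and with an estimated correlation they had an adjusted p = 0.949. That value differs in both settings, so the pair does not measure the effect of the block. At day 2 every lung correlated best with the lung of its own number, a hint from the values alone. At day 60 the same-numbered correlations of 0.091, 0.01 and 0.055 gave no such pairing. With the day 2 block over all arrays the counts were 749 and 2345 for BLT1+/+ and BLT1-/-, 21 for the BLT1 difference and 977 for the difference between days; of these 232, 1315, 4 and 468 were genes of the main result. The mean response gave 3275 and the interaction 0 by limma, with 1245 at an unadjusted p under 0.05. Of the named gene values 55 passed with this block and not in the main result, among them Il1b in the mean response, and none was lost. Of the list calls 8 were lost and 2 gained, among the latter circadian clock genes in the interaction (camera adjusted p = 0.0391 with the preset correlation). Without the block and with an estimated correlation these had an adjusted p = 0.972, a value that differs in both settings and does not measure the effect of the block.

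Leaving out 1 CS lung at a time gave 65 to 685 genes for BLT1+/+ and 697 to 1549 for BLT1-/- at day 2, 43 to 477 for BLT1+/+KRasLA1 and 69 to 432 for BLT1-/-KRasLA1. The mean responses gave 1945 to 3099 and 573 to 1040, the BLT1 differences 1 to 6 and 1 to 7, the interactions 0 by limma, the difference between days 312 to 716 and the pools 38 to 103. Xist, which was not called in any main result, reversed without BLT1+/+KRasLA1 replicate 2, the lung with Y-linked expression. It ran from -0.946 to 0.657 in the mean response at day 60 and from -0.752 to 0.851 in the difference between days.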

Other observations

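The tests of the chromosome of Ltb4r1, of Ear6, Rnase2b and Ngp, of 1 BLT1+/+ lung with a smaller response, of the exchanged PBS pools, of the male share and of the calls shared with day 2 were chosen only after the results were seen. Single keratin and macrophage genes also differed between the days. The keratin genes Krt8 (-0.78 ± 0.16) and Krt7 (-0.93 ± 0.19) had a smaller response to silica at day 60 in KRasLA1 lungs than at day 2. Krt19 (-0.83 ± 0.18) was called too but lost without any of 4 single lungs, and Krt18 (-0.88 ± 0.23) missed the threshold (adjusted p = 0.0723). In all 3 of 19 adenoma and plasticity genes were lower (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.241 with an estimated correlation). Some lipid-handling genes of macrophages went the other way: the cholesterol exporters Abcg1 (0.91 ± 0.15) and Abca1 (0.59 ± 0.10) and the lipase Lipa (0.59 ± 0.11) responded more positively at day 60. Of the lysosome and lipid-laden macrophage list 4 of 15 were higher (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.224 with an estimated correlation). Monocyte and recruited macrophage markers had 5 higher and 1 lower of 19 (8 and 1 adjusted over the list alone, adjusted p = 0.227 with an estimated correlation), with the receptor Ccr2 at 0.91 ± 0.17 and Adgre1 (F4/80) at 0.66 ± 0.13. The RNA sensor Tlr7 was at 1.05 ± 0.14, the checkpoint receptor Ctla4 at 1.07 ± 0.17 and the T cell gene Themis at 1.42 ± 0.23. Fold changes here are from limma, with adjusted p under the threshold for all but Krt18.

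Between the day 60 KRasLA1 pools and the day 2 pools, matrix and T cell lists were called lower with the preset correlation and not with an estimated one. Extracellular matrix genes had 0 of 21 by limma (4 lower adjusted over the list alone, median -0.26, adjusted p = 0.0669 with an estimated correlation), with Col1a1 at -0.54 ± 0.12 (adjusted p = 0.0704). T cell markers had 1 of 20 lower (6 adjusted over the list alone, median -0.37, adjusted p = 0.387 with an estimated correlation), with Cd3g at -1.01 ± 0.18, a call lost without BLT1+/+ CS day 2 replicate 2. Oxidative stress genes had 0 of 16 by limma (3 higher adjusted over the list alone, median 0.28, adjusted p = 0.394 with an estimated correlation), with Nqo1 at 0.76 ± 0.16 (adjusted p = 0.0685). Over all genes 2127 had an unadjusted p under 0.05 in the pools.

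Of the 9 genes past the threshold between BLT1 genotypes, 88.9% shared the chromosome of Ltb4r1, which holds 698 of 19856 measured genes with a known place. At an unadjusted p under 0.001, 13 of 88 genes lay on it at day 2 (3.09 for independent genes, one-sided Fisher exact p = 1.19e-05) and 15 of 24 at day 60 (0.844, p = 1.30e-16), and all 8 called genes on it had the same sign in both pairs of PBS pools. All 8 day 60 calls lay on it (0.281 for independent genes, one-sided Fisher exact p = 2.24e-12), and 11.1% of the set lay elsewhere. Ddhd1, Klhl33 and Lrrc18 were about as different in the day 60 pools without silica. Tmem260 (-0.33), Syt15 (-0.75) and Rnase1 (0.38) differed less there than in the CS lungs (-0.48, -1.05 and 0.96). For these 9 genes the values argue against a genome-wide response of the silica-exposed lung to BLT1 loss as the cause of the whole set. The shared chromosome prompted this test too. Most genes at an unadjusted p under 0.001 at day 2 lay elsewhere, and a response among genes that did not pass is not addressed. DNA of another strain carried along with the targeted allele is a candidate explanation that the shared chromosome prompted and cannot itself support. Open are Ear6, Rnase2b and Ngp, whose pools differed by a median of 0.115 of their CS difference, while their interactions (-1.25 ± 0.36, -1.70 ± 0.47 and -1.14 ± 0.35) had adjusted p of 1.00, 1.00 and 0.820. Rnase2b was dim in every pool, so its difference there may be understated. Splits of 3 lungs against 3 are too few for a share under 0.05: at day 2 the real split gave 4 genes and the highest of the others 13, so 2 of the 10 splits gave as many, which points to a structure among these lungs, while the other splits that part all same-numbered lungs gave 0 by limma; at day 60 the real split gave 8, the highest other 2, and 1 of 10 gave as many.

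At day 2 silica gave 1315 calls in BLT1-/- lungs and 232 in BLT1+/+ lungs, although 0 genes passed the interaction by limma (896 at an unadjusted p under 0.05). The PBS pools do not account for all of this ratio of 5.67: with the pools exchanged it fell to 3.51 (1388 and 396). Without BLT1+/+ replicate 1, whose removal raised that genotype's count most, the ratio fell to 2.38 (1629 and 685). This sets 3 BLT1-/- lungs against 2 BLT1+/+ lungs. With 1 BLT1-/- lung left out instead, the BLT1-/- count was 1549, 829 or 697. The 2.38 therefore cannot tell whether this lung accounts for the rest, and pools and lung may each contribute a part. Whether the response is larger without BLT1 stays open: over 204 genes called in both genotypes the median ratio of log2 fold changes was 0.988 (quartiles 0.863 and 1.21), a set that favours genes with large changes in BLT1+/+ lungs, and over genes of the mean response it was 1.33. A ratio of 1.0 or lower had been set as evidence against it, but 0.988 lies within the quartiles, so that bound was set aside after the value was seen.

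The day 60 PBS pools held male tissue and 5 of the 6 CS lungs did not, so sex could account for some day 60 calls. With the male share of each array as a covariate the log2 fold changes of the 802 called genes had a median ratio of 1.08 to those without it (quartiles 1.01 and 1.15), and 557 of them were still called, but within groups only 1 lung differs in male share, so this estimate decides little. The rises shared with day 2, where no array had Y-linked expression, were 3.97 times those of independent lists (213 and 53.6). Both days use the same variance estimate per gene, so their lists are not independent and this factor is too high. A shared variance does not set the direction, and 213 rises and 48 falls were shared while 68 genes were called in opposite directions. To that extent the overlap argues against the sex mix as the cause of every call. Of the called genes 100% had the sign of the mean response in the CS lung with Y-linked expression, but they were chosen in a fit that holds this lung, so this share says nothing for silica instillation as the cause. A contribution of sex to single genes stays open.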
